A study of Pseudomonas aeruginosa PA14 with 16 samples.

How the data were processed

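RNA from Pseudomonas aeruginosa strain PA14 was measured by strand-specific paired-end RNA sequencing. Per the labels, cells were grown in LB medium, mixed with an RNA-stabilising reagent at harvest, opened with lysozyme, and the RNA was purified on RNeasy columns and treated with DNase. Each RNA then went through a custom-made protocol or a commercial kit (Ribo-off, Vazyme) that removes ribosomal RNA, and directional libraries were made with NEBNext Ultra II reagents. The 16 libraries form 4 groups, which are custom protocol or kit in exponential or stationary phase, each with 2 biological and 2 technical replicates. A library is written here as b1t2, for example, for biological replicate 1 and technical replicate 2. The labels do not say at which step the technical replicates were split.

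The deposited values are read counts per feature, with no normalisation. The authors checked reads with FastQC 0.11.4, aligned them with Bowtie2 2.2.6 to the PA14 chromosome and counted them with featureCounts 1.6.4. Per the file headers, the count was strand-specific and of read pairs. A read that the alignment reported at several places, or that overlapped several features, was counted at each of them. A ribosomal RNA (rRNA) read is therefore counted at every copy of the gene where the alignment reported it, and features that overlap share counts. Whether the alignment reported a single place or every place for such a read was not established.

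The files list 6026 features by identifier, start, end, strand and length, with no gene names. Of these, 5977 carry a PA14 locus tag and 49 another identifier. The RefSeq gene table at hand, with 6051 genes, is of another PA14 assembly, and 0 of the 6026 identifiers occur in it. No gene names are therefore given. The gene lists that had been chosen by gene symbol, among them ribosomal proteins, quorum sensing, iron uptake and secretion systems, could not be matched to the files and were not tested.

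Features were sorted into classes by identifier, length and position. The 5900 PA14 tags of at least 100 nt whose length is a multiple of 3 are called coding-length features; they hold no untranslated regions. The 67 PA14 tags under 100 nt are called short features. The rRNA features are 4 pairs, the members of a pair on the same strand (1 pair on the forward and 3 on the reverse strand), each with a member of 1526 nt and a member of 2884 or 2891 nt, 472 nt apart. Exactly 4 RefSeq genes have a length of 2891 nt, and all are rRNA genes, while none has a length of 2884 or 1526 nt. The third rRNA, 5S, could not be picked out. Feature PA0826.2 is 353 nt long, the length of ssrA (transfer-messenger RNA, tmRNA) in the RefSeq table, where 1 pseudogene has the same length. These identities rest on length and position alone.

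Groups, comparisons, tests and most alternatives were chosen before the data were examined, and so was the rule for features named in the text. That rule took the abundant RNAs, the largest rises and falls with the same sign in both methods or both phases, with a mean log2 CPM (counts relative to library size) of at least 4 for phase, and the smallest p of the interaction. Because no names could be matched, at most 2 identifiers that rose and 2 that fell are printed per comparison, and other features are given by coordinates. Runs of neighbouring features, windows along the chromosome and their alternatives were chosen after seeing the data, since the gene lists could not be used.

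The 2 technical libraries of each biological replicate were summed, which gave 8 sums, 2 per group. Library sizes and TMM factors came from coding-length features. Features were kept by filterByExpr with a minimum count of 10, which left 6006 features, 5886 of them coding-length. The edgeR 4.0.16 quasi-likelihood test was run on 1 fit of all 4 groups (R 4.3.3), and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. The 6 contrasts were stationary minus exponential in each method, custom minus kit in each phase, the mean of these last contrasts, and the interaction, which is the phase change with the custom protocol minus that with the kit. A ± beside a log2 fold change is the standard error from this fit.

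The design text implies that one RNA preparation was treated in both ways. The difference between biological replicates 1 and 2 over 4309 coding-length features correlated between the methods at r = 0.906 in exponential and 0.912 in stationary phase, and at -0.0667 and -0.0768 between the phases of one method. The numbers therefore pair the samples between methods within a phase. Counts with the RNA preparation as a block are given beside the counts of features and runs that differ between the methods, and the paired values for runs, feature classes and features called in both phases were added after the unpaired ones were seen. That fit has 2 residual degrees of freedom in place of 4. The main fit treats the paired sums as independent, so the 4 behind its phase p-values are not fully independent. The replicate number as a block over all groups, as written beforehand, gave 546 features in exponential and 916 in stationary phase between the methods.

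Shares are percentages of all counts of a sum, with the SD over the 2 biological replicates. They were compared by two-sided exact permutation tests, within each phase (smallest possible p 0.333) and over both phases with phase as stratum (36 arrangements, smallest possible p 0.0556). The sums were permuted freely within a phase, which ignores the pairing by RNA preparation. Swaps within pairs alone would leave fewer arrangements and a higher smallest p. Single libraries have Wilson intervals at 95% confidence, which cover counting error only, since reads without molecular identifiers are not independent molecules. Detection, at a count of at least 10, was counted after thinning every sum to the same total of all counts. Runs are at least 5 tested coding-length features in a row on one strand with gaps of at most 50 nt. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, and with fry. Windows of 50 kb were compared with all tested coding-length features by one-sided Fisher's exact tests, adjusted over the 131 windows.

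Library totals ranged from 8471744 to 14214828 counts, and 13565288 to 23804520 counts per sum fell on coding-length features. All 6026 features had a count in at least 1 library. The steps were tested on simulated data with the same groups, with 5998 features tested. All sums were drawn independently, without the pairing by RNA preparation, and features were independent beyond the planted changes. Far fewer phase changes were planted than were called in the real data, and the fit with the block was not run. The rates below hold for that setting only. For the mean of both method contrasts edgeR called 56% of the planted changes of 0.5 log2, 98% of those of 1 and 100% of those of 2, and 4.32% of its calls were false. For the phase change with the custom protocol the shares were 36%, 92% and 100%, with 6.76% false, and with the kit 24%, 86% and 98%, with 7.94% false. With no interaction planted it called 0. Of 10 planted runs with a change of 1 log2, camera with the preset correlation called 10, fry 8 with 2 others, and camera with the estimated correlation 0.

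Alternatives were DESeq2 1.42.0, other scaling factors and filters, coding-length features alone, the 2 groups of a contrast alone, the 16 libraries as separate samples, limma-voom with duplicateCorrelation, replicate blocks, length offsets, single technical libraries, other thresholds and leaving out each sum in turn. Those added after seeing the data were the counts of the 4 rRNA copies divided by 4, leaving out the 2 custom libraries with the most rRNA, the block by RNA preparation together with length offsets, other definitions and tests of runs, other windows, and detection at equal coding-length totals. No library was left out of the main results.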

Results

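The study put RNA from growing and from stationary PA14 cultures through 2 ways of removing abundant RNA before sequencing. It asked how a protocol made for the organism compares with a reference kit, and the 2 growth phases give a biological contrast that can be read with each. Each of the 4 groups (custom or kit, exponential or stationary) held 4 libraries from 2 biological replicates, so n = 2 sums of technical libraries per group. Library totals ranged from 8471744 to 14214828 counts.

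With the custom protocol nearly all counts fell on coding-length features, in both growth phases. With the kit, rRNA took a larger part of the counts, and so did 2 further abundant RNAs. The kit shares of these 2 were higher in stationary phase, and that of rRNA in exponential phase. The rRNA share was lower with the custom protocol in both phases, and the long rRNA members made up most of the difference. All shares below are means with SD over n = 2 biological replicates.

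Coding-length features held 97.6% ± 1.5 of the counts with the custom protocol in exponential phase and 96.4% ± 1.55 in stationary phase. With the kit they held 68.98% ± 1.92 and 65.99% ± 0.790. The rRNA features held 1.77% ± 1.53 and 2.61% ± 1.68 with the custom protocol and 20.7% ± 2.35 and 15.1% ± 0.324 with the kit. For each of these shares both custom sums lay on one side of both kit sums in each phase. The exact permutation p was 0.333 within each phase and 0.0556 over both phases, each the smallest possible when the pairing is ignored. An rRNA read may have been counted at a single copy or at every copy. If at a single copy, the shares above hold and the divided rRNA shares below are too low. For the other case, the rRNA shares were also computed with the counts of the 4 copies divided by 4. They then came to 0.450% and 0.667% with the custom protocol and to 6.14% and 4.27% with the kit, and the coding-length shares to 98.95% ± 0.371 and 98.36% ± 0.310 with the custom protocol and 81.65% ± 0.577 and 74.45% ± 1.09 with the kit.

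**Figure D1:**
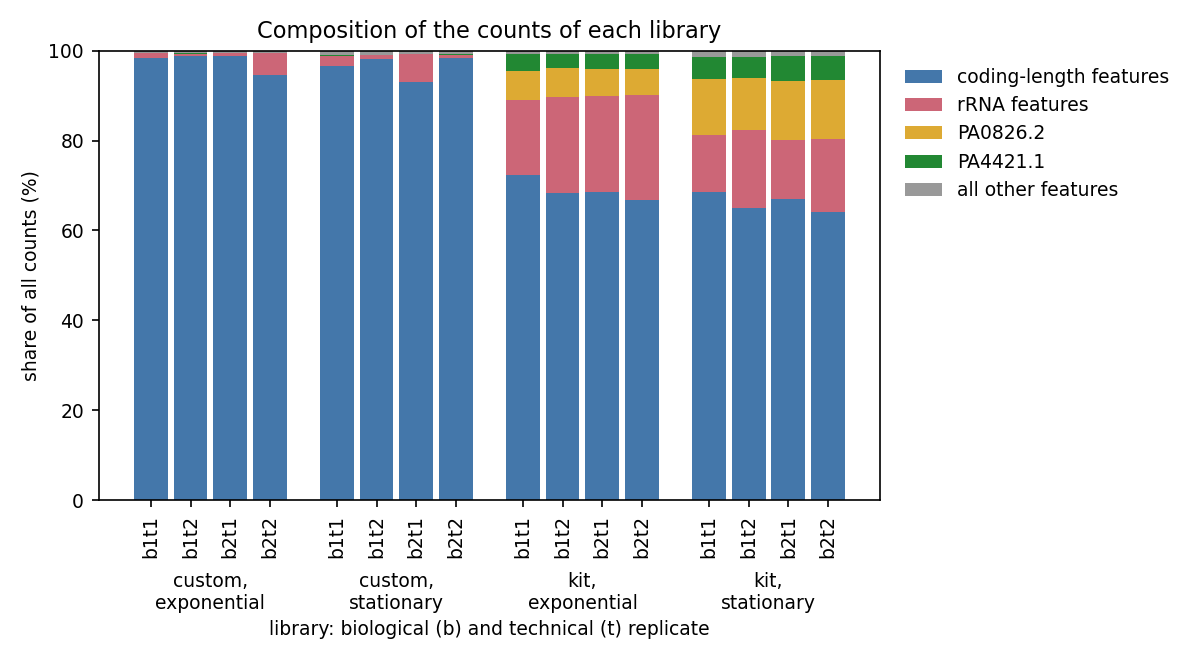
Share of all counts (%, linear axis from 0) in each of the 16 libraries, stacked by feature class, with libraries grouped by method and growth phase. Coding-length features hold 93.0 to 98.9% of the counts in the 8 custom libraries and 64.1 to 72.4% in the 8 kit libraries.

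The difference between the methods was larger for the long than for the short rRNA members, though no test compared these 2 kinds. The 4 members of a kind are copies that draw on the same reads, so they are not separate measurements. Over both phases the long ones ran only from -4.36 to -4.25 log2, custom minus kit. The 4 long members, at 735093–737983, 4952288–4955171, 5536295–5539185 and 6312766–6315656, together held 0.952% ± 0.946 and 1.36% ± 0.871 of the counts with the custom protocol (exponential, stationary) and 19.3% ± 2.06 and 14.1% ± 0.239 with the kit. Their median log2 fold change, custom minus kit over both phases and relative to coding-length counts, was -4.28 (-5.17 to -3.89 without any one sum), and all 4 were past the threshold (largest adjusted p 0.00358, edgeR), also in each of the 8 fits without 1 sum. In the single phases all 4 were called too, but in 2 of these 8 fits in exponential phase and in 6 in stationary phase none was. The 4 short members, of 1526 nt each, held 0.815% ± 0.588 and 1.25% ± 0.813 with the custom protocol and 1.39% ± 0.287 and 1.03% ± 0.0851 with the kit. For these the median log2 fold change was -0.68 (-1.21 to -0.38 without any one sum) and none of the 4 was past the threshold (largest adjusted p 0.322). With the RNA preparation as a block it was -0.88 and all 4 were past the threshold for the mean of both phases; 4 were in exponential phase and 0 in stationary phase. The stratified exact permutation p of the share of the short members was 0.667.

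PA0826.2 (4749730–4750082, 353 nt, the length of tmRNA) held 6.20% ± 0.260 of the counts with the kit in exponential phase and 12.5% ± 0.762 in stationary phase. With the custom protocol it held 0.000280% ± 0.000267 and 0.00152% ± 0.00114, from 9 to 570 counts per library. The kit mean was 22170 times the custom mean in exponential phase and 8190 times in stationary phase, but the custom means rest largely on single libraries, exponential b2t2 with 78 counts and stationary b2t1 with 570. In exponential phase the log2 fold change was -14.86 ± 1.20, and it was -16.48 without custom b2 and -14.11 without custom b1; in stationary phase it was -13.44 ± 1.14, and -14.60 and -12.79 without these. Its log2 fold change, custom minus kit over both phases, was -14.15 ± 0.83 (adjusted p 4.21e-05). PA4421.1 (5119887–5120095, 209 nt) held 3.36% ± 0.188 and 5.15% ± 0.471 with the kit and 0.0857% ± 0.0105 and 0.129% ± 0.000493 with the custom protocol, a ratio of 39.2 and 40.0. Its log2 fold change was -5.76 ± 0.18 (adjusted p 2.29e-06). For both RNAs the stratified exact permutation p was 0.0556, the smallest possible when the pairing is ignored.

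Which method detected more coding-length features depended on the depth that was matched, and the differences were small. With every sum thinned to 20383176 counts, 5859 ± 8.49 of 5900 coding-length features had at least 10 counts with the custom protocol in exponential phase and 5846.5 ± 6.36 in stationary phase. The kit gave 5830 ± 11.3 and 5825 ± 11.3. The custom means were higher by more than the SD in both phases, but at that total more of the custom counts are coding. With sums thinned to 13565288 coding-length counts, which was added after seeing the data, the custom protocol gave 5810 ± 21.2 and 5801 ± 17.0 and the kit 5823 ± 18.4 and 5827 ± 8.49. The sums then overlapped in exponential phase and were lower with the custom protocol in stationary phase. No test was run on these values. Technical libraries of one biological replicate correlated at r = 0.996 to 0.998 over coding-length features. Their coefficient of variation beyond counting error was 2.30%, against 13.8% between biological replicates.

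Growth phase changed most of the transcriptome. Features moved in both directions, and how many rose relative to how many fell depends on the scaling. The change was nearly the same whichever method removed the abundant RNA, and in some runs neighbouring features on one strand changed together, though how many runs were called depended on the test, from 0 with an estimated correlation to 85. Some stretches of the chromosome held more rises or more falls than the rest, often with both directions in one stretch.

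With the custom protocol 4085 of 6006 features differed between stationary and exponential phase, 2047 higher and 2038 lower, and 1938 of them by more than 1 log2. With the kit 4000 differed, 2066 higher and 1934 lower, 1848 by more than 1 log2. Of these, 3750 were called with the same sign in both methods and 5 with opposite signs; none of the 5 was past the threshold in the unpaired interaction (smallest adjusted p 0.182), and all 5 were with the RNA preparation as a block (largest adjusted p 0.000140), which was added after seeing the data. These 5, at 682911–683729, 2544083–2546152, 2665032–2665102, 4722774–4723724 and 5510221–5510292, are named after their values were seen. Another 330 were called with the custom protocol alone and 245 with the kit alone. Across 5886 coding-length features the phase log2 fold changes of the methods correlated at Pearson r = 0.987 and Spearman rho = 0.977, and r was 0.975 to 0.981 without any one sum. Features are not independent replicates, and the methods share RNA preparations, so this agreement covers the method and not a second set of cultures. The median absolute difference was 0.09 log2, and 37 features differed by more than 1. The median phase change of all features was 0.04 in each method; with upper-quartile factors it became 0.18 and 0.17, and the calls became 2405 higher and 1764 lower with the custom protocol and 2404 and 1693 with the kit. Past 1 log2, with the main scaling, 864 were higher and 1074 lower with the custom protocol and 839 and 1009 with the kit.

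**Figure D2:**
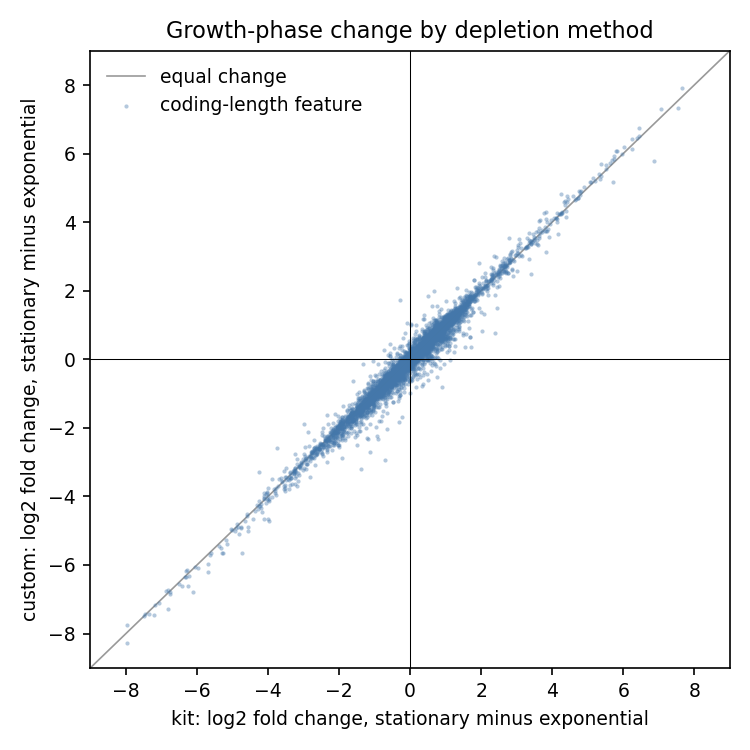
Log2 fold change, stationary minus exponential, of coding-length features with the kit (horizontal axis) against the custom protocol (vertical axis), 1 point per feature. The points lie along the diagonal, with Pearson r = 0.987 across 5886 features.

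The largest rises lay close together. PA14_33270 (2911261–2912025) rose by 7.92 ± 0.55 log2 with the custom protocol and 7.66 ± 0.54 with the kit (adjusted p 1.59e-05 and 1.85e-05). PA14_33250 (2909570–2910037) rose by 7.34 ± 0.48 and 7.55 ± 0.50 (adjusted p 1.24e-05 and 1.39e-05). Among the falls, PA14_20200 (1740354–1742264) changed by -8.28 ± 0.32 and -7.96 ± 0.32 (adjusted p 1.41e-06 and 1.70e-06). PA14_13830 (1189694–1190377) changed by -7.75 ± 0.20 and -7.96 ± 0.21 (adjusted p 4.57e-07 and 4.91e-07). The rises start from levels near 1 CPM in exponential phase, for PA14_33270 0.798 ± 0.702 with the custom protocol and 1.05 ± 0.758 with the kit. Without any one sum its change ran from 7.20 to 9.28 and from 7.10 to 8.71, and that of PA14_33250 from 6.77 to 8.25 and from 7.06 to 8.37. For each of the 4 the sums of the phases did not overlap in either method.

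PA0826.2 changed from exponential to stationary phase by 2.64 ± 0.79 log2 with the custom protocol (adjusted p 0.0193), and by 1.22 ± 0.70 with the kit, which was not past the threshold (adjusted p 0.158). The spread behind both standard errors is shared by all groups, the custom sums with few counts included. The kit share was 2.01 times as high in stationary phase without overlap of the sums. The kit value ran from 1.10 to 1.30 without any one sum. Without any one sum the custom value ran from 1.48 to 4.26, and in 2 of these 8 fits it was not past the threshold. The custom value rests on few counts, 9 to 570 per library, and became -0.51 with technical libraries 2 alone. PA4421.1 was higher by 0.75 ± 0.21 and 0.82 ± 0.21 (adjusted p 0.0146 and 0.0102), and in each method it was not past the threshold in 2 of the 8 fits without 1 sum. No rRNA feature was past the threshold between phases in either method, with medians of 0.69 (long) and 0.80 (short) with the custom protocol and -0.25 and -0.23 with the kit. The custom medians rest on single sums: without any one sum they ran from -0.25 to 2.46 (long) and from -0.15 to 1.85 (short), and without custom exponential b2 all members were past the threshold.

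Runs of neighbouring coding-length features were tested as sets, a choice made after seeing the data. Of 121 runs with 797 features, camera with the preset correlation called 39 with the custom protocol, 6 up and 33 down, and 38 with the kit, 6 up and 32 down. The 38 called in both methods were 6 up and 32 down. With the estimated correlation camera called 0 (lowest adjusted p 0.486 and 0.561), with 8 and 7 runs at an unadjusted p under 0.05, and fry called 85 and 84. The values that follow are mean log2 fold changes with the SD over members, custom protocol first. The estimated-correlation p beside them are unadjusted, and no adjusted one was past the threshold.

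The run at 5160079–5163895 (5 features) rose by 5.52 ± 0.246 and 5.71 ± 0.659, with adjusted p 1.95e-07 and 5.88e-08 at the preset correlation and unadjusted estimated-correlation p 0.0563 and 0.0523. The run at 227383–233525 (7 features) rose by 2.83 ± 0.175 and 2.72 ± 0.0896, with adjusted p 2.16e-07 and 3.09e-07 and unadjusted estimated-correlation p 0.0762 and 0.0783. The run at 785708–799926 (5 features) rose by 2.95 and 2.93. The other runs called up by camera with the preset correlation, at 1253836–1259346, 689773–696198 and 699647–707056, had means between 0.99 and 1.57. Runs it did not call include some with larger means, such as 3338466–3343233 (4.56 and 4.46) and 2950112–2956296 (3.07 and 3.15).

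The run at 1736789–1744455 (6 features) changed by -7.08 ± 0.771 and -6.73 ± 0.748, with adjusted p 6.07e-10 and 5.19e-10 and unadjusted estimated-correlation p 0.0407 and 0.0404. The run at 581088–590077 (11 features) changed by -6.65 ± 0.507 and -6.65 ± 0.496, with adjusted p 2.13e-18 and 7.98e-20 and unadjusted estimated-correlation p 0.0388 and 0.0364. The run at 1803293–1816675 (8 features) changed by -3.67 ± 0.389 and -3.62 ± 0.399, with adjusted p 1.75e-14 and 1.26e-14 and unadjusted estimated-correlation p 0.00985 and 0.00789. Runs at 101659–110560 and 3810500–3819820 changed by -4.00 and -3.66 with the custom protocol and by -3.68 and -3.57 with the kit. Every member of each run named here moved in the direction of its run past the threshold in both methods.

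**Figure D3:**
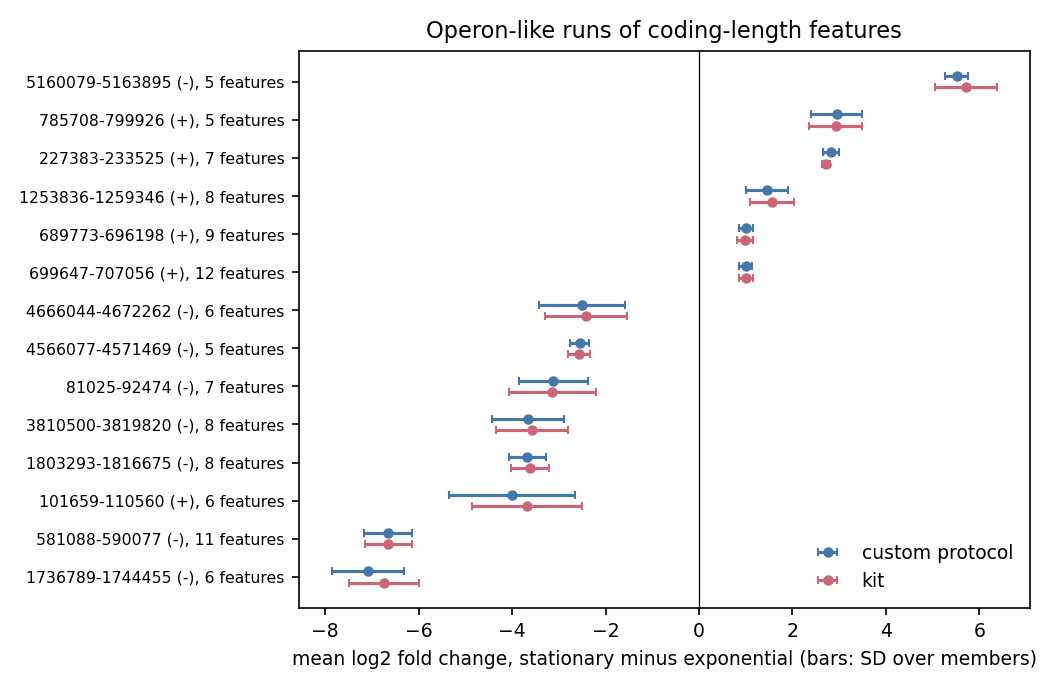
Mean log2 fold change, stationary minus exponential, of the named runs of neighbouring coding-length features in each method, labelled by coordinates, with the SD over members. Values range from 5.71 (5160079–5163895, kit) to -7.08 (1736789–1744455, custom).

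In windows of 50 kb, also chosen after seeing the data, 723 coding-length features rose and 956 fell by more than 1 log2 in both methods. These are 12.3% and 16.2% of those tested. Rises were enriched in 14 of 131 windows and falls in 8 (Fisher's exact test, adjusted p under the threshold). Enriched rises came to 8 windows without the stationary b2 sum of the custom protocol, to 8 without that of the kit, and to 9 without the 2 custom libraries with the most rRNA; with 100-kb windows, 6 were enriched in rises and 4 in falls. In the window at 2950001–3000000 all 20 tested features rose, with a median of 3.78 with the custom protocol and 3.83 with the kit (adjusted p 6.35e-17). In the window at 3800001–3850000, 23 of 42 fell and 0 rose, with medians of -1.59 and -1.50 (adjusted p 1.42e-06). Other enriched windows held both directions, such as 100001–150000 (23 fell, 10 rose) and 3000001–3050000 (12 rose, 11 fell). Neighbouring features can share a transcript, so the features in a window are not independent.

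**Figure D4:**
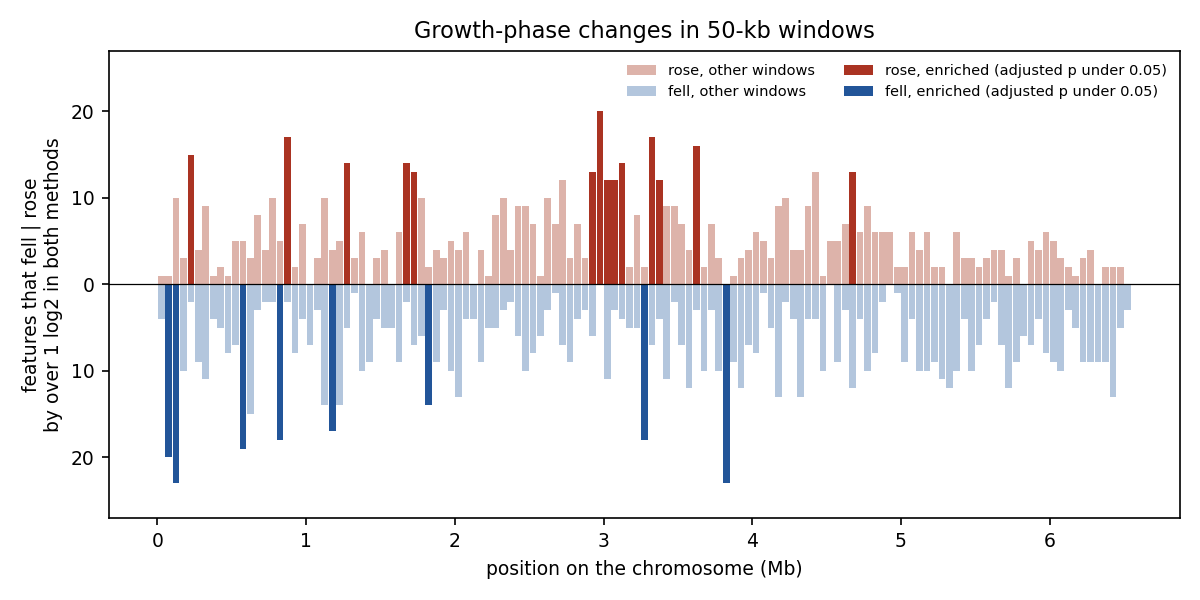
Number of coding-length features per 50-kb window along the chromosome (Mb) that rose (upward bars) or fell (downward bars) by more than 1 log2 from exponential to stationary phase in both methods, with enriched windows in darker colour. The highest upward bar, 20 features, is the window at 2950001–3000000, and the lowest downward bars, 23 features each, are those at 100001–150000 and 3800001–3850000.

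Between the methods, most coding-length features differed by less than 0.5 log2, and many of these small differences were past the threshold once samples were paired by RNA preparation. Apart from the rRNA and the 2 abundant RNAs above, features under 100 nt stood out, and most of these were lower with the custom protocol. Features with an identifier other than a PA14 tag were also more often lower than higher. Coding-length features that differed did so in both directions.

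In exponential phase 390 of 6006 features differed between custom protocol and kit, 180 higher and 210 lower with the custom protocol. In stationary phase 625 differed, 255 higher and 370 lower, and for the mean of both phases 1269, 588 higher and 681 lower. The balance of directions follows the scaling: for the mean, RLE factors gave 670 higher and 632 lower and upper-quartile factors 490 and 749. With the RNA preparation as a block the counts were 2793 (1505 higher, 1288 lower), 3025 (1534 and 1491) and 3576 (1794 and 1782), and all features of the unblocked calls were kept with the same sign. Without any one sum the unblocked counts were 156 to 332, 223 to 442 and 778 to 978. A total of 342 features were called in both phases with the same sign, 159 higher and 183 lower, and 1 with opposite signs; with the block these were 2215, 1200 higher and 1015 lower, and 20. Of 5886 coding-length features, 89.6% lay within 0.5 log2 of equality for the mean of both phases. Their method log2 fold changes in the 2 phases, which share no library, correlated at r = 0.827 across features.

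Feature length separated the short RNAs from the rest. Of the 63 tested short features with a PA14 tag, 2 were higher and 50 lower with the custom protocol over both phases, with a median of -1.58 log2. With the block 3 were higher and 53 lower. Of 46 features of any length with another identifier, PA4421.1 among them, 8 were higher and 22 lower, with a median of -0.39. With the block these were 12 and 26. Among all features under 100 nt the median was -1.37, against -0.18 from 100 to 200 nt and between -0.02 and 0.04 in every longer bin. The short features at 734791–734863 (73 nt) and 6315990–6316063 (74 nt), which lie between the members of rRNA pairs, changed by -3.58 ± 0.08 and -3.55 ± 0.09 (adjusted p 1.47e-06 for each). PA3366.1 (1768473–1768572, 100 nt) was higher with the custom protocol by 3.11 ± 0.24 log2 (adjusted p 0.000184), and PA14_36820 (3281521–3281688, 168 nt) by 2.64 ± 0.14 (adjusted p 2.26e-05). All 4 had the same sign past the threshold in each phase.

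**Figure D5:**
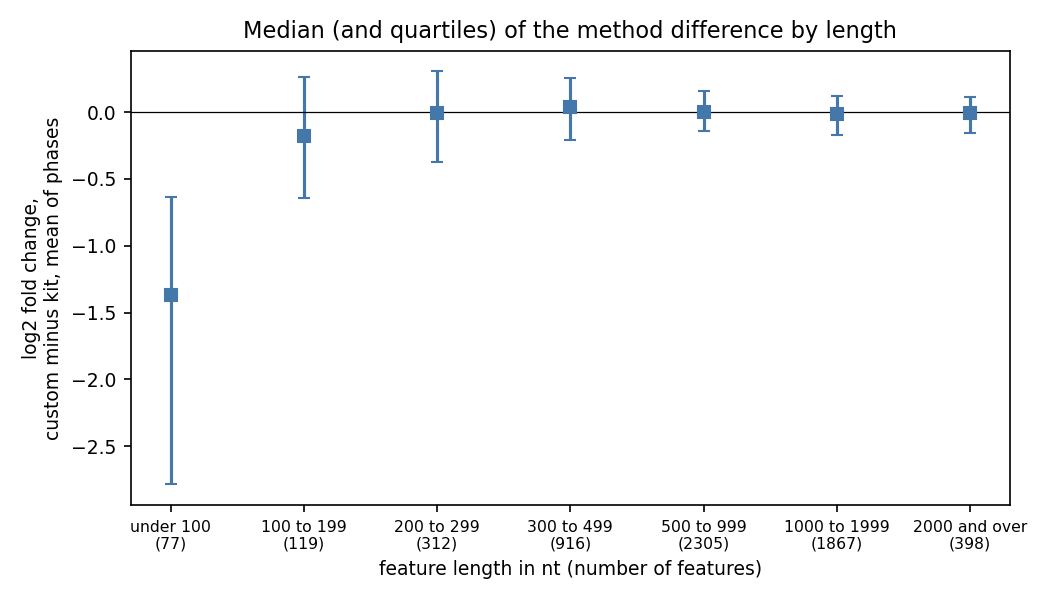
Log2 fold change, custom minus kit over both phases, of tested features by length bin in nt, with the median and the quartiles of each bin. The median is -1.37 below 100 nt and lies between -0.02 and 0.04 in each bin from 200 nt up.

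The interaction asks whether the choice of method changes the growth-phase comparison. With edgeR 2 of 6006 features were past the threshold and 131 had an unadjusted p under 0.05. DESeq2 called 14 and limma-voom 11. With the RNA preparation as a block edgeR called 219, 48 higher and 171 lower, with the 2 among them. Both lie at 5555928 on the forward strand and overlap, so they share counts. PA4704.1 (116 nt) rose with the kit by 3.60 ± 0.22 log2, and its change with the custom protocol was 0.22 ± 0.21 (-0.04 to 0.55 without any one sum), an interaction of -3.37 ± 0.31 (adjusted p 0.0309). PA4704-PA4705 (325 nt) changed by 3.93 ± 0.22 with the kit and by 0.76 ± 0.21 with the custom protocol (0.48 to 1.12 without any one sum), an interaction of -3.17 ± 0.30 (adjusted p 0.0309). Neither was past the threshold in 6 of the 8 fits without 1 sum, with technical libraries 1 alone, or with the replicate number as a block.

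Runs were also compared between the methods. The 0 calls of camera with the estimated correlation decide little here. In the simulated phase contrast that setting called 0 of 10 planted runs with a change of 1 log2. Without pairing, camera with the preset correlation called 0 of 121 runs in exponential phase, in stationary phase and for their mean, with 8, 9 and 8 at an unadjusted p under 0.05. Fry called 0, with 15, 19 and 28 at an unadjusted p under 0.05, and camera with the estimated correlation called 0, with 0 at an unadjusted p under 0.05. With the RNA preparation as a block, camera with the preset correlation called 1, 1 and 2, fry 13, 20 and 20, of which 12 were up each time, and camera with the estimated correlation 0, with 0 at an unadjusted p under 0.05. For the interaction camera with the preset correlation called 5, all down, with the estimated correlation 0 (2 at an unadjusted p under 0.05), and fry 0 (3 at an unadjusted p under 0.05). With the block these were 5, all down, 0 (1 at an unadjusted p under 0.05) and 0 (21 at an unadjusted p under 0.05).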

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

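The tests of the residual rRNA in this part were chosen after its values were seen. For 17 quantities in the 4 groups, 68 sets of 4 libraries, the highest or lowest library was compared with the others by Dixon's criterion (0.829). Chance alone marks about 1 in 20 such sets; 6 of the 68 were marked, and some of them share counts.

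Library b2t2 of the custom protocol in exponential phase stood apart from its group with 94.6% of counts on coding-length features (Wilson interval 94.61 to 94.64) and 4.81% on rRNA (4.79 to 4.82). In the kit's exponential group, library b1t1 stood apart with 3.77% of counts on PA4421.1 (3.76 to 3.79) and 0.202% on short features (0.199 to 0.204). Library b1t1 of the custom protocol in stationary phase stood apart with 4.17 CPM, relative to coding counts, at 734791–734863 and 6.25 CPM at PA4704-PA4705. The last 2 rest on low counts, and no explanation was tested for the last 4 values.

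Residual rRNA in the custom libraries ranged from 0.440% to 6.19%, with the highest values in exponential b2t2 and stationary b2t1. Reads carried over from kit libraries, as the only source, would keep the kit's ratio of short to long members. The lowest custom ratio (0.734) was 8.98 times the highest kit ratio (0.0818). The ratio leaves room for a part from such reads, and these 2 libraries had the lowest ratios of their groups (0.734 and 0.872). A large part would also have brought PA0826.2, with 6.20% and 12.5% of kit counts. It held 0.000677% and 0.00401% of the counts in these libraries. The RNA preparation does not account for the whole spread, since technical libraries of one preparation differed on average by 2.95 percentage points, 1.52 times the difference between preparations (1.94). Incomplete removal in single reactions may explain it. In 2 of 2 phases the library with the most rRNA also had the highest share of PA0826.2 in its group. A small part of reads carried over from kit libraries would raise PA0826.2 too, so this match does not tell the 2 explanations apart. PA4421.1 did not go along: its share was the lowest of the group in both libraries (0.0782% and 0.124%), though more rRNA lowers every other share. Incomplete removal stays a hypothesis, and no biological explanation was tested.

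In the unpaired fit the phase change differed between the methods by the interaction test at PA4704.1, with -3.37 log2, and PA4704-PA4705, with -3.17, which overlap. Their change in stationary phase was 3.60 and 3.93 with the kit and 0.22 and 0.76 with the custom protocol. With the RNA preparation as a block the values were -3.36 and -3.15, and 219 features were past the threshold, 48 higher and 171 lower. The smallest adjusted p of these, 1.57e-09, belongs to the feature at 2544083–2546152, with -1.12 ± 0.05 log2, which was chosen after its values were seen. No explanation was tested.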

How the results depend on the processing

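The shares of rRNA, PA0826.2 and coding-length features kept their direction under every alternative run. The phase counts stayed within 1.5 times under all but the limit on log2 fold change, and every other scaling or filter on low counts kept all 6 counts within 1.5 times. The cause of the changes below was not tested, except that stricter thresholds, fewer samples and fewer features leave less to call.

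Between methods (exponential, stationary, mean), the counts of 390, 625 and 1269 became 1545, 1936 and 2584 with 16 libraries as separate samples, and 2793, 3025 and 3576 with the replicate block within phase. With length offsets added to that block they were 2776, 3074 and 3566. Limma-voom gave 710 and 953 in the single phases, and the stationary groups alone 248. Leaving out 1 sum, with the lone sum taken to vary like the other groups, gave 156 to 332, 223 to 442 and 778 to 978. At an adjusted p under 0.01 they were 164, 206 and 530. Past an absolute log2 fold change of 1 they were 147, 184 and 169, and the phase counts 1938 (custom) and 1848 (kit).

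The interaction, 2 features, became 14 (DESeq2), 36 (16 libraries), 11 (limma-voom), 219 (replicate block within phase) and 183 (that block with length offsets). It became 0 with coding-length features alone, the replicate number as a block with or without length offsets, technical libraries 1 alone, an adjusted p under 0.01, or without the 2 custom libraries with most rRNA. Leaving out 1 sum gave 0 to 2. PA0826.2 reversed between phases with the custom protocol, to -0.51, with technical libraries 2 alone.

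Runs changed with the test. Camera with the estimated correlation called 0 for the phase contrasts and the interaction. It also called 0 of 10 planted runs in simulation. Fry, which asks only whether the members changed, called 85 (custom), 84 (kit) and 0 (interaction). With gaps of at most 20 nt 25 were called with the kit. With at least 8 members 11 (custom), 9 (kit) and 3 (interaction) were called. The interaction's 5 runs became 8 with at least 4 members, 2 with the replicate number as a block, 3 with the block within phase and length offsets, 2 with technical libraries 2 alone, and 6 to 15 without 1 sum.

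Depth limits detection. With at least 1 count the custom protocol (exponential, stationary) and then the kit detected 5898.5, 5898.5, 5897.5 and 5897 coding-length features. With at least 50 counts they detected 5456, 5440.5, 5342 and 5318. With at least 10 counts, single libraries thinned to one total detected 5707.5, 5706.5, 5643.75 and 5644. With equal coding totals, chosen after seeing the data, 5810, 5801, 5823 and 5827 were detected. The order of the means reversed, but in exponential phase the sums of the methods overlapped.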

Other observations

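The shuffled-block test, the planted trends, the subsets of features other than those by count, and the limit to paired splits in this part were chosen after the results were seen, and the rule for reading the rotation test was changed then. Stationary transcriptomes were more concentrated on a few genes than growing ones. The 10 most abundant coding-length features held 8.41% ± 0.442 of coding counts with the custom protocol in exponential phase and 20.3% ± 1.02 in stationary phase (SD, n = 2). With the kit they held 8.18% ± 0.261 and 19.3% ± 0.687. Short features, those under 100 nt, more often rose than fell in stationary phase, with 37 up and 1 down of 63 with the kit and 22 up and 6 down with the custom protocol.

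Phase changes followed position on the chromosome: features far from coordinate 1 rose relative to near ones, with a slope of 0.196 log2 per Mb in both methods (0.173 to 0.215 without any one sum). More gene copies near the replication origin in growing cells is a candidate explanation, but the test written for it beforehand was missed: 5.79% of rotations of the feature order with the custom protocol and 5.52% with the kit gave a slope as high, against a bound of 5, and 9.07% and 7.78% among features of low count. By that rule the explanation was to be rejected, and the verdict was changed to open only after the value was seen, because the rotations as high were shifts of at most 5.78% of the chromosome, which keep a true trend, and trends of the same size planted on shuffled blocks of 50 features passed the bound in 52.5% and 47.5% of 200 trials. In a second test, chosen after the first was missed, 0 of 1000 shuffles of such blocks gave a slope as high (highest 0.193 and 0.183). Of all subsets rotated, those of higher count (5.54% and 5.61%), the forward strand (25% and 24.6%, slope 0.146 and 0.142), the reverse strand (10.1% and 10.0%, slope 0.242 and 0.246) and features within 2 log2 (9.11% and 8.35%, slope 0.117 and 0.119) missed the bound too, while the lower coordinates (4.50% and 3.82%) and the upper (4.97% and 4.91%), each rotated within itself, met it. Gene dosage and regulation of large regions therefore cannot be told apart here, and a DNA count of both phases would be needed.

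Coding-length features that differed between the methods were weighed against technical explanations. A trend with feature length in a single direction does not account for most of them. The Spearman correlation was -0.0675 over coding-length features. Of the called features, 91.5% were kept with length offsets (92.9% with the RNA preparation as a block both times). These tests cannot see an effect of length that acts in both directions, which stays open. Of 119 tested features from 100 to 200 nt, other identifiers included, 24 were called higher and 40 lower over both phases. From 1000 to 2000 nt these were 106 and 158 of 1867. Depth does not account for most of the called coding-length features, since 88.7% stayed called with the same sign after thinning to equal coding totals. Of the 8 splits of the 8 sums into 4 and 4 that part all 4 pairs of one RNA preparation, fitted with growth phase as a covariate, 1, the real one, gave as many features (1495) and the highest other gave 0, but 8 are too few for a share under 0.05. The 26 that part fewer pairs gave at most 1, and the split by growth phase, which cannot be fitted with that covariate and was fitted without it, gave 4199, a structure of the samples; no biological explanation was tested.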
